A study of Homo sapiens with 2 samples.

How the data were processed

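Total RNA from H1 cells, an established human embryonic stem cell line, was measured on 1-colour (Cy3) bead arrays. In such arrays each probe sits on many beads, and its level is the mean brightness of those beads. There were 4 arrays, 2 for each of 2 growth media, and the design text describes the pair of each medium as biological replicates. Both arrays of a medium are held under the same sample label. The header of an N2B27 array reads MN2B27, which was taken to be the same medium. Per the labels' protocols, 400 ng of RNA was amplified linearly with an in vitro transcription of 7 h, and cells were collected 4 days after passaging. RNA was purified on columns with DNA digestion.

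The authors deposited for each array a mean signal intensity per probe, a bead variation on the same intensity scale (standard deviation per the column name, but whether it is a standard error is not stated), and a detection score. The detection score is a fraction from 0 to 1, per the file headers and the values, and it rises with the signal, so that it was read as 1 minus a detection p. BeadStudio 1.5 is named in the submitters' processing notes. The background and normalization steps are not given in the sources used here. The signals did not appear to be background-subtracted: the lowest value on an array lay between 114.7 and 138.3. A second table that the authors deposited holds 1 processed intensity per medium and probe, in whole numbers. Its values followed the mean of the medium's 2 arrays (Pearson r = 0.999969 across probes in N2B27 and 0.999896 in conditioned medium), less a median offset of 200.85 and 195.35 intensity units. The lowest value listed was 31 in each medium, and the rule by which other cells were left blank is not known here. The column medians were 368 for N2B27 and 363 for conditioned medium. Its scale is linear and its direction is given by the columns, but its scaling between media stays unknown. It was used only as an alternative.

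Each array held 24354 rows. Of these, 24350 were probes named by a GI number, a former sequence identifier of NCBI, and 4 were rows with other names (lysA, pheA, thrB and trpF), which were left out of the tests. The last letter of a probe name follows the manufacturer's scheme: S for a gene with a single known transcript, A for a probe shared by all transcripts of a gene, and I for a probe specific to an isoform. The files do not pair the GI numbers with gene symbols. None of the row names occurred in the reference gene table used here. Therefore no gene is named, the 26 gene lists fixed before the data were examined had 0 members that could be matched, and the planned tests of those lists with camera and fry were not run. The planned rule for named genes (the 12 highest rises and 12 deepest falls past the test with array values that did not overlap) needed symbols. Only its first 2 probes in each direction, by fitted difference, are given, by their identifiers. The other parts of that rule (list members and 7 genes to be named in any case) also needed symbols and name nothing here. The genomic positions of the probes are likewise not given.

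The background was corrected and the arrays were normalized with the neqc method of limma 3.58.1 in R 4.3.3: normexp correction with the background estimated from the detection scores, an offset of 16, quantile normalization and log2 values. Probes with a detection score over 0.99 on at least 2 of the 4 arrays were tested, 11061 in all, and 13289 were not. A linear model with the medium as its only term was fitted per probe with limma (lmFit and eBayes), and a probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. Differences are N2B27 minus conditioned medium on the log2 scale. A probe with no detection score over 0.99 on either array of a medium is described as not well above background there. Its fold is given as a lower bound, from the bright medium's mean and the dim medium's mean of the higher of 2 levels per array: the probe's own and the lowest among detected probes. The bound is a point estimate that holds under the main correction and offset only, and other corrections can give a smaller fold.

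The number of arrays limits the precision. A simulation made 10 data sets of 11061 probes with 50 changed probes per fold size. The test recovered 6.2% of 1.5-fold changes, 69.2% of 2-fold changes, 95.4% of 3-fold changes and 99.2% of 4-fold changes, with 4.5% false calls. At most 2 probes were called when no probe was changed. Each probe's spread was drawn at random from the variance distribution that limma fitted, without regard to its level, and errors were independent and normal. These rates describe the test under its own model and may not hold for the real arrays. The array headers number the replicates 1 and 2 in each medium. The labels do not say that a number marks a shared batch, so the main model has no block, and the block was an alternative added after seeing the data. The other alternatives were no background correction, an offset of 50, median centring or cyclic loess in place of quantile normalization, no filter on dim probes, detection on all 4 arrays, an intensity trend in the variance, a 2-fold minimum, the authors' processed table, and leaving out each array.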

Results

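H1 human embryonic stem cells were grown on Matrigel, a basement membrane extract, in parallel in 2 media, and their transcripts were compared. The first was medium conditioned by inactivated mouse embryonic fibroblasts (MEF), which release factors that feed stem cell cultures. The second was N2B27, a defined medium made with the N2 and B27 supplements, 0.5% albumin and 20 ng/ml of the growth factor FGF2. Each medium was represented by 2 arrays. A detection score over 0.99 was reached by 11002 and 10723 of the 24350 probes on N2B27 replicates 1 and 2, and by 10936 and 10782 probes on conditioned-medium replicates 1 and 2. The median signal was 249.65 and 260.3 intensity units on the N2B27 arrays and 254.6 and 224 on the conditioned-medium arrays, and the median of the deposited bead variation was between 4.67% and 5.09% of the signal; whether it is a standard deviation of the beads or a standard error of their mean is not stated. Conditioned-medium replicate 2 was the dimmest array.

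The normalized levels of most tested probes were close in both media, although small changes would mostly go undetected with this number of arrays. Across the 11061 tested probes, which are not independent replicates, normalized log2 levels correlated with r = 0.9926 between the 2 N2B27 arrays and r = 0.9906 between the 2 conditioned-medium arrays. Between media r ranged from 0.9805 to 0.9839, below both values within a medium. The difference between replicate arrays had an SD of 0.247 in N2B27 and 0.277 in conditioned medium on the log2 scale. From those spreads alone, the difference between the means of the media would have an SD of 0.186 across probes. The observed SD was 0.336. The median difference of all tested probes was 0.01, a value that quantile normalization holds near 0.

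Of the 11061 tested probes, 422 (3.82%) differed between the media in limma's test at an adjusted p under 0.05. In N2B27, 186 probes were higher and 236 were lower. The changes were mostly moderate: the median fitted difference among called probes was 1.95-fold and the smallest was 1.55-fold. The fitted difference was at least 2-fold for 187 called probes, 61 higher and 126 lower. For 40 of these, one medium was not well above background and the lower bound of the fold was under 2. With such probes counted only by their bounds, 47 probes were at least 2-fold higher and 100 were at least 2-fold lower. Counted in this way, 12 probes were at least 4-fold lower in N2B27 and 0 were at least 4-fold higher. All 422 called probes had array values that did not overlap between the media, which held for 47.3% of all tested probes, where chance gives 33.3%. At an unadjusted p under 0.05 there were 1881 probes by the same limma test. Fewer probes were called when either N2B27 array was left out. The spread was then estimated from the conditioned-medium arrays alone, and the cause of the lower count was not tested. Testing all 24350 probes, dim ones included, gave 118 calls, and without background correction, where folds are smaller, 7 higher and 35 lower calls reached a fitted difference of 2-fold.

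**Figure D1:**
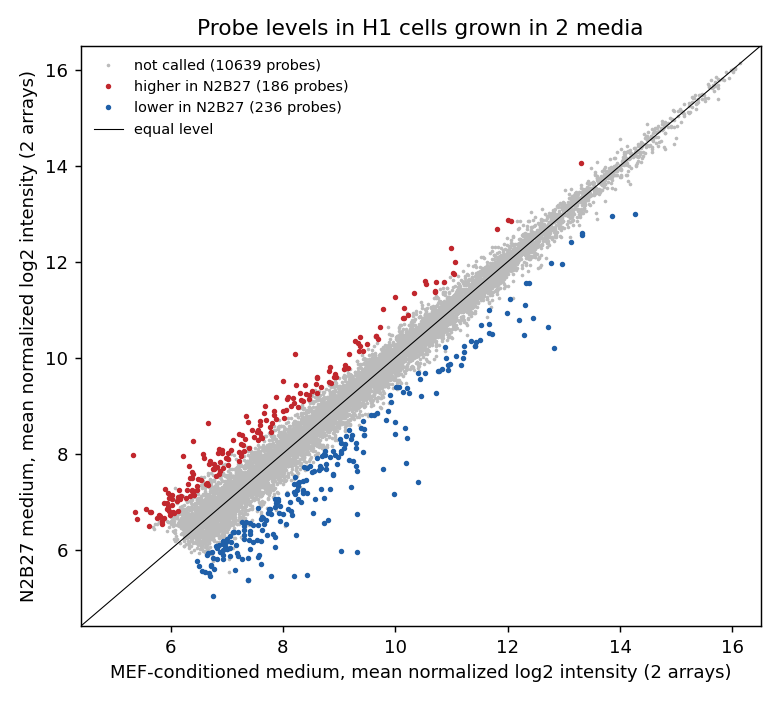
Mean normalized log2 intensity of each tested probe in N2B27 medium (vertical axis, 2 arrays) against MEF-conditioned medium (horizontal axis, 2 arrays), with a line at equal levels and one point per probe. Most probes lie near the line, while 186 probes called higher in N2B27 lie above it and 236 called lower lie below it; points at low levels on one axis are not well above background there, and their distance from the line is not an exact fold.

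Some called probes passed the detection score of 0.99 on both arrays of one medium and on neither array of the other, which leaves open a low level there. Among the probes called higher in N2B27, 39 were not well above background on either conditioned-medium array, and the lower bounds of their rises ran from 1.05-fold to 2.90-fold with a median of 1.35-fold. Among the probes called lower in N2B27, 61 were not well above background on either N2B27 array. The lower bounds of these falls ran from 1.03-fold to 7.47-fold with a median of 1.499-fold.

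The following 2 falls and 2 rises were taken by fitted difference. For 3 of the 4 probes one medium was not well above background, so that their rank among the changes is not established. Their lower bounds hold under the main background correction only. Each adjusted p below tests the fitted difference against 0 and does not test the bound. For probe GI_34147575-S, the log2 level was 5.96 ± 0.47 (SD, n = 2 arrays) in N2B27, where it was not well above background, and 9.33 ± 0.04 in conditioned medium, so that it was at least 7.47-fold lower in N2B27 (limma, adjusted p = 0.00124). Probe GI_37549314-S was also not well above background in N2B27, at 5.96 ± 0.02 against 9.03 ± 0.20 in conditioned medium. Its level was at least 6.08-fold lower in N2B27 (limma, adjusted p = 0.000625). Probe GI_29126235-S had 7.96 ± 0.003 in N2B27 and 5.33 ± 0.43 in conditioned medium, where it was not well above background. It was at least 2.90-fold higher in N2B27 (limma, adjusted p = 0.00262). Probe GI_31317226-S had 8.63 ± 0.03 in N2B27 and 6.66 ± 0.01 in conditioned medium, and all 4 arrays detected it. Its log2 rise was 1.97 (SE 0.13), or 3.91-fold (limma, adjusted p = 0.00124). In the table of 1 processed intensity per medium that the authors deposited, GI_31317226-S was listed at 386 in N2B27 and 88 in conditioned medium, GI_34147575-S at 44 and 634, and GI_37549314-S at 43 and 515. GI_29126235-S was listed there at 236 in N2B27 and was blank in conditioned medium. The folds and their lower bounds depend on the background correction. Without it, the log2 differences were 1.07 for GI_29126235-S, 1.02 for GI_31317226-S, -1.76 for GI_34147575-S and -1.53 for GI_37549314-S. All 4 were still called, but for the 3 probes given by a bound these differences were smaller than the bound.

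The 3 kinds of probes contributed calls at overlapping rates. Probes of genes with a single known transcript were called in 335 of 9108 cases (3.68%, 95% exact binomial interval 3.30% to 4.09%), 147 higher and 188 lower. Probes shared by all transcripts of a gene were called in 54 of 1263 cases (4.28%, 3.23% to 5.54%), 26 higher and 28 lower. Isoform-specific probes were called in 33 of 690 cases (4.78%, 3.31% to 6.65%), 13 higher and 20 lower. These intervals treat probes as independent, and the rates were not tested against each other.

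When the tested probes were ranked by mean level and divided into quintiles, the dimmest quintile held 167 calls (75 higher and 92 lower) and the brightest held 29 (10 higher and 19 lower). In the brightest quintile, 9 called probes had a fitted fall of at least 2-fold and 1 had such a rise. Brightness also reflects how well a probe binds, so that the quintiles do not order transcripts by abundance. The gradient with brightness depended on the processing. Without background correction, the quintiles from dimmest to brightest held 77, 127, 122, 130 and 105 calls, and with an intensity trend in the variance they held 108, 166, 131, 109 and 103. With detection required on all 4 arrays, which leaves out probes detected in 1 medium only, they held 56, 144, 85, 71 and 37. Under the offset of 50, median centring and cyclic loess, the counts fell from dimmest to brightest as in the main fit.

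**Figure D2:**
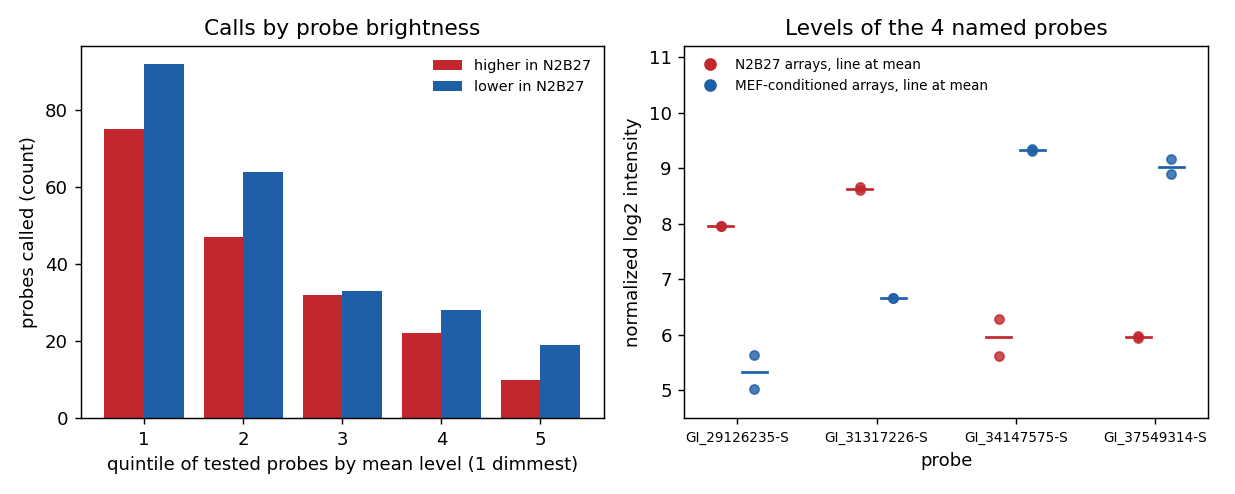
Left, the number of called probes (vertical axis) in each quintile of the tested probes by mean level (horizontal axis), as bars for probes higher and lower in N2B27, falling from 75 and 92 in the dimmest quintile to 10 and 19 in the brightest. Right, normalized log2 intensity (vertical axis) of the 4 named probes, 2 higher and 2 lower in N2B27, with a point per array and a line at each medium's mean; the arrays of the media do not overlap for any of the 4 probes.

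In the authors' deposited table, 12603 rows had a value in both media, 754 in N2B27 alone, 808 in conditioned medium alone and 10189 in neither. Of the 422 called probes, 399 had both values there, and all 399 differed in the same direction as in the test. The other 23 were listed in the medium with the higher level only. This table comes from the same arrays and is not independent of the test. Across tested probes with both values, its log2 ratios correlated with the fitted differences at r = 0.9937.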

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

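Row lysA, one of the 4 rows not named by a GI number, exceeded the detection score of 0.99 on 3 of the 4 arrays, which set it apart because it lies outside the probes that were tested. Its signal was 252.8 and 254.2 intensity units on the N2B27 arrays and 247.5 and 227.9 on the conditioned-medium arrays, and it was listed at 43 in both media in the authors' deposited table. The other 3 rows of this kind exceeded the score on 0 arrays. The score of lysA was not on the scale of the probes' scores. On N2B27 replicate 1, lysA scored 0.998 at 252.8, while probe GI_34147575-S scored 0.987 at a higher signal of 265.3. By signal, lysA lay near the median of each array, such as 249.65 on N2B27 replicate 1. Detection of lysA above background is therefore not established.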

How the results depend on the processing

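With other corrections (no background correction, an offset of 50), other scalings (median centring, cyclic loess), detection on all 4 arrays or an intensity trend, 393 to 617 probes were called, each count within 1.5 times the reported 422; of the 422, the same probes called again numbered 422 under median centring and under cyclic loess, 411 with the offset of 50, 350 with the trend, 328 without background correction and 287 with detection on all 4 arrays. Detection on all 4 arrays left some of the 422 untested, among them the 39 and 61 not well above background in 1 medium. The count of 287 therefore mixes probes left out with probes not called again. The trend gave 281 higher probes against 186, and the cause was not tested. Without a filter on dim probes 118 were called (38 higher, 80 lower), of which 115 were among the 422; the probes added are dim. With a 2-fold minimum 187 remained (61 higher, 126 lower). Calls with a fitted difference of at least 2-fold numbered 25 higher and 87 lower with the offset of 50, and 7 and 35 without background correction. Leaving out 1 array gave 47 to 452 calls, 8 to 212 higher and 39 to 240 lower. The lone array was assumed to vary like the other medium's pair. The 2 lowest counts came from leaving out an N2B27 array (105 without replicate 1, 47 without replicate 2); the cause was not tested. A replicate block on the header numbers, added after seeing the data, gave 491 calls (221 higher, 270 lower), 405 of them among the 422; differences between replicates 1 and 2 correlated with r = 0.20 between the media, and with 2 pairs the numbers are not taken to pair the cultures. The 4 named probes kept their direction and their call in each alternative in which they were tested. With all 24350 probes, the difference between replicate arrays had an SD of 0.2956 in N2B27 and 0.2959 in conditioned medium. Between the conditioned-medium arrays r was 0.9926, and between media it was 0.9888 to 0.99. The difference between the means of the media had an SD of 0.2886. Means of 2 arrays vary less than single arrays, so that value cannot be set directly against the SDs between replicates. The tests of gene lists and their alternatives were not run. Signal over background limits the folds of dim probes, since the 4 named probes had log2 differences from -1.76 to 1.07 without background correction and from -3.37 to 2.63 with it.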

Other observations

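Of the tests below, only those of background correction and scaling and of probes near background were fixed before their result was seen. The test of single arrays, the count by bounds, that of the sibling probes and the splits of the arrays were chosen after it.

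A group of 109 reference sequences had both a probe shared by all transcripts of the gene and an isoform-specific probe among those tested, which gives 2 measurements of one reference sequence on the same arrays. In 6 of these 109 pairs at least 1 probe was called, and in all 6 the other probe had a difference in the same direction. In 3 pairs both probes were called, all 3 in the same direction. In the 103 pairs with no called probe, 68 had differences in the same direction. Across the 109 pairs, which are not independent replicates, the differences between media correlated with Spearman's rho = 0.496 and Pearson's r = 0.717. The highest rho in 10000 random pairings was 0.344 and the highest r was 0.451 (permutation test, one-sided p = 0.0001 for each, the smallest that these pairings can give). Over the 103 pairs with no called probe, rho was 0.403 and r was 0.434, against highest values of 0.356 and 0.388 in 10000 random pairings of those pairs. Within these 109 pairs, errors confined to 1 probe of a pair are therefore unlikely to account for the differences as a set. With 1 array left out, the lowest rho was 0.352, without conditioned-medium replicate 1. Only 6 of the pairs held a called probe. The 335 called probes of genes with a single known transcript were outside this comparison. An error shared by both probes stays open. So does a difference between cultures or arrays that is not due to the medium, which both probes would share.

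Large falls in N2B27 outnumbered large rises: 67.4% of the 187 called changes with a fitted difference of at least 2-fold were falls. With probes not well above background in one medium counted only by their bounds, the share was 68%. Against background correction and scaling between arrays as the whole cause, the share among called changes was 69.3% to 83.3% under the other corrections and scalings. In the authors' deposited table it was 63% (95% exact binomial interval 56.9% to 68.7%, treating probes as independent) over a different set, all tested probes with a ratio of at least 2-fold, called or not. Among probes detected on all 4 arrays the share was 67.3% (57.8% to 75.8%), which speaks against undetected probes as the whole cause. Detected probes can still lie near background. GI_31317226-S was detected on all 4 arrays, yet its log2 rise was 1.97 with background correction and 1.02 without it. The filter therefore cannot decide whether probes near background contribute. With one array left out the lowest share was 60.6% (53.7% to 67.1%), without conditioned-medium replicate 2. A hypothesis that stays untested is that conditioned medium supplies signals that N2B27 lacks, so that transcripts dependent on them may fall further than others rise. Naming the probes' genes could not decide it. The albumin and added FGF2 of the conditioned medium are not given here, and N2B27 has its own supplements. The media may therefore differ in more than conditioning.

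The number of called probes was compared with the other ways to split the 4 arrays into 2 and 2. Of the 3 splits, 1, the real one, gave 422 calls or more, and the highest of the others gave 0. The splits are too few for a share under 0.05. At an unadjusted p under 0.05 the split by replicate number gave 335 probes, the crossed split 131 and the split by medium 1881. In the other splits the difference between media adds to the residual spread, which lowers their counts. They are therefore not a baseline for the split by medium.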
